A study of Mus musculus with 2 samples.

How the data were processed

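Small RNAs of 15 to 40 nt were gel-purified from 5 pooled pairs of testes per genotype at 11 days after birth, and libraries from an Illumina small RNA kit were read on a Genome Analyzer II, per the labels' protocols. The design text states that exons 2 to 4 of Tdrkh, which hold the start codon, were excised, on a mixed C57Bl6/129 background. The submitters' processing notes name Bowtie and the mouse build mm9; versions, adapter trimming and filters are not given in the sources used here. The deposited values are raw read counts of distinct sequences, 1 table per library; the tables held sequences of 18 to 40 nt, each listed once, with 60973266 reads in Tdrkh-/- and 43172204 in Tdrkh+/-. Sequences read once carried 13.1% and 18.5% of reads.

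No genome sequence was used here. All sequences were matched exactly, over their whole length and on both strands, to the GENCODE M21 transcripts (GRCm38) with a matcher written in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Numba 0.67.0; figures were drawn with Matplotlib 3.10.9. Coordinates are those of GRCm38. Of all reads, 51.5% in Tdrkh-/- and 46.4% in Tdrkh+/- matched a transcript on either strand. Reads of 18 to 25 nt in microRNA hairpins were counted as microRNA reads (2478003 and 2342972). Matches to ribosomal, small nuclear, small nucleolar and other structural RNA genes were set aside; the annotation holds no nuclear tRNA and no full ribosomal RNA precursor. The rest was analysed as 24 to 30 nt (piRNA size) and 31 to 37 nt (long). Sequences in more than 20 genes on 1 strand counted as repeat-derived. Reads in several genes were divided equally among them.

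Levels are reads per microRNA read, and ratios are Tdrkh-/- over Tdrkh+/-. With 1 library per genotype no test was run. Shares carry 95% Wilson intervals and ratios exact conditional binomial intervals, which cover counting error only, since reads without molecular identifiers are not independent molecules. A count of 0 was set to a floor of 3 counts per library for a ratio, which is then a bound. Overlaps of 1 to 24 nt between opposite-strand reads were weighed by the product of their counts on 1 transcript per gene. Sharing of 5′ ends was measured on the first 24 nt, with starts shifted by 1 to 10 nt as the comparison. A list's median log2 ratio was placed among 10000 random lists of the same size drawn from the same 10 bins of level, as a description; lists with under 5 measured members gave values alone. Ribosomal S6 kinase genes were left out of the ribosomal protein list, which narrows its name pattern.

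Named microRNAs are the 10 most abundant and the 10 highest and 10 lowest ratios among those with at least 200 reads. Named genes are the 10 most abundant hosts and the 5 highest and 5 lowest ratios among those with at least 500 reads of 24 to 30 nt, with Tdrkh and 2 to 4 abundant members of each list. A single one of the genes so chosen is not reported here. These rules, the gene and microRNA lists, the length windows and all alternatives but those named below as added were chosen before the data were examined. The fixed lists covered the let-7, mir-17 to mir-92a, mir-34, X-linked, mir-290 to mir-302, Dlk1-Dio3, mir-181 and mir-10 groups and cell type microRNAs, and for host genes the piRNA pathway, ribosomal proteins, histones, Sertoli, Leydig and peritubular cells, spermatogonia, early meiosis and names with pachytene or piRNA. The alternatives tried were each distinct sequence counted once, sequences read once left out, narrower windows, lower count minimums, other scalings, assignment of microRNA reads by their first 18 nt and, added after seeing the data, sequences in 1 gene alone, scaling per transcript-matching read, sequences found in 1 library alone left out and, for repeats, each distinct sequence counted once, as found and in 10 random thinnings to equal numbers of long reads.

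The matcher was checked against a plain string search on 120 sequences, with 0 strands that differed. Gene ratios were tested on simulated data, Poisson counts drawn for the 4053 genes from their real means with 200 of them changed. All 100 genes changed 4-fold passed the 2-fold mark, 0 of 100 changed 1.5-fold did and 0 unchanged genes did. Of the intervals, 95.0% held the true ratio. The draws held no variation between animals or libraries, so they check the calculation and not how reliable the 2-fold calls are. LINE-1 protein sequences used in the closing section were typed from general knowledge, and reads of at least 26 nt were counted when their whole translation matched them. Regions of the genome, introns and transposon families by name were not analysed here.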

Results

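Small RNAs were sequenced from testes of mice at 11 days after birth, 1 library from Tdrkh-/- and 1 from Tdrkh+/- animals, each made from 5 pooled pairs of testes. Tdrkh encodes a Tudor and KH domain protein of the mitochondrial surface, and the series asks about its part in primary piRNA production, the stage at which long single-stranded precursors become the small RNAs bound by PIWI proteins. The Tdrkh-/- library held 60973266 reads of 12118721 distinct sequences, and the Tdrkh+/- library held 43172204 reads of 11808018 distinct sequences. The 1132430 sequences found in both libraries carried 57.2% of the Tdrkh-/- reads and 51.3% of the Tdrkh+/- reads. With 1 library per genotype no difference had a replicate check, and all intervals cover counting error only.

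The excised part of Tdrkh gave no reads in the knockout. Exons 2 to 4, on chromosome 3 from 94422802 to 94424690 (GRCm38), had 0 sense reads in Tdrkh-/- and 15 in Tdrkh+/-, of which 12 lay in exon 2 and 3 in exon 4. The other exons of Tdrkh (ENSMUSG00000041912.12) had 722 and 1081 sense reads of sequences that match no other gene, most of them in the last exon with 545 and 982. Reads of 24 to 30 nt sense to Tdrkh had a log2 ratio of Tdrkh-/- to Tdrkh+/- of -1.42 (-1.63 to -1.21), and those of 31 to 37 nt one of -0.19 (-0.39 to 0.01).

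Small RNAs of piRNA size were scarcer and longer RNAs were far more frequent in the Tdrkh-/- testis. Reads of 24 to 30 nt made up 24.2% of the Tdrkh-/- library and 71.7% of the Tdrkh+/- library, whereas reads of 31 to 37 nt made up 53.2% and 15.2%. The most frequent length above 23 nt was 35 nt in Tdrkh-/- and 27 nt in Tdrkh+/-. MicroRNAs, which are made without the piRNA pathway, served as the reference: per microRNA read there were 5.88 reads of 24 to 30 nt in Tdrkh-/- and 13.1 in Tdrkh+/-, a ratio of 0.447 (95% exact interval 0.447 to 0.447). For 31 to 37 nt the values were 13.1 and 2.79, a ratio of 4.68 (4.68 to 4.69). Over 24 to 40 nt together the ratio was 1.33 per microRNA read and 0.998 per read listed. The window of 26 to 28 nt differed more, with a ratio of 0.273, as did the window of 33 to 36 nt, with a ratio of 6.91. Reads of 18 to 23 nt outside microRNAs and structural RNAs were also more frequent per microRNA read in Tdrkh-/-. Their ratios ran from 1.48 at 22 nt to 3.07 at 18 nt. Single lengths of 25 to 29 nt lay below 1, while the ratio was 1.17 at 24 nt and 1.07 at 30 nt.

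**Figure D1:**
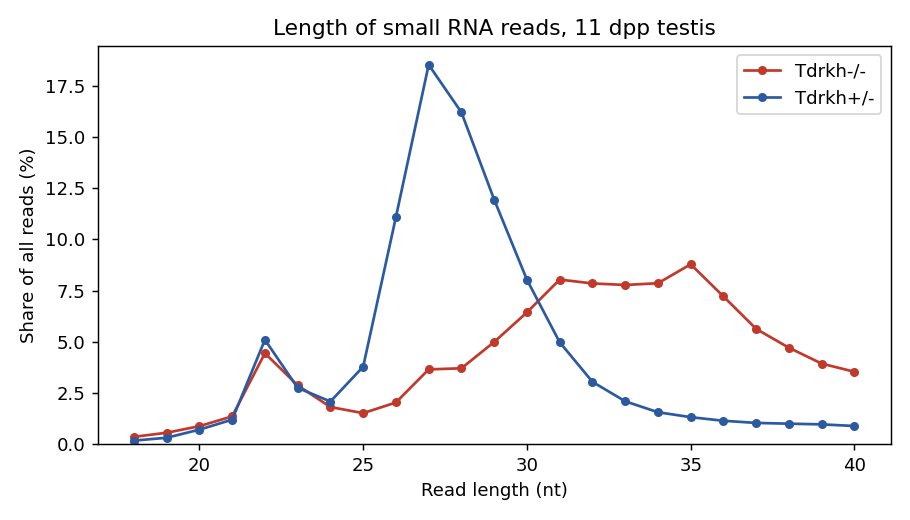
Share of all reads (percent) at each read length (nt) in the Tdrkh-/- library (red) and the Tdrkh+/- library (blue). The highest point above 23 nt lies at 35 nt in Tdrkh-/- and at 27 nt in Tdrkh+/-.

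Long RNAs of the knockout shared 5′ ends with piRNA-size RNAs of the heterozygote more often than shifted starts did. Of the Tdrkh-/- reads of 31 to 37 nt, 70.7% shared their first 24 nt with a 24 to 30 nt read of Tdrkh+/-, against a median of 46.3% and a highest value of 50.04% when the start was shifted by 1 to 10 nt. With U required at the position the gap was smaller, 72.2% at the 5′ end against a median of 60.6% and a highest value of 66.8% at shifted starts. They shared it with a 24 to 30 nt read of their own library in 63.9% of cases, and long Tdrkh+/- reads did so within their library in 66.0%. At the 28590 5′ ends with at least 50 reads in each library, the mean read length of an end had a median of 32.2 nt in Tdrkh-/- and 28.9 nt in Tdrkh+/-. Reads from the same 5′ end were longer in Tdrkh-/- at 91.7% of these ends, with a median difference of 2.49 nt and a middle range of 0.888 to 4.42 nt. With each distinct sequence counted once, the share of long reads that had a matching 5′ end was lower in Tdrkh-/- (31.7%) than in Tdrkh+/- (39.4%).

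Both libraries carried the base preference of primary piRNAs, a U at the 5′ end. For an A at position 10, the preference of secondary piRNAs, no background share was measured, so the values compare the libraries alone. A 5′ U was found in 75.7% of the 24 to 30 nt reads of Tdrkh-/- and in 82.8% of those of Tdrkh+/-, and in 73.7% and 73.6% of the 31 to 37 nt reads. The shares at 31 to 37 nt were 72.1% and 65.9% with each distinct sequence counted once, 82.7% and 74.8% with sequences that match a single gene, and 73.9% and 76.4% without sequences read once. Among reads without a 5′ U, A at position 10 was found in 53.1% and 39.4% at 24 to 30 nt and in 63.7% and 45.5% at 31 to 37 nt. This gap was 2.21 points among 24 to 30 nt sequences that match a single gene (35.1% and 32.8%), against 13.7 points among all. The shares at 24 to 30 nt were 39.1% and 34.1% with each distinct sequence counted once. Reads with a 5′ U had A at position 10 in 41.45% and 32.96% at 24 to 30 nt and in 38.05% and 34.22% at 31 to 37 nt. The higher share in Tdrkh-/- was therefore not limited to reads without a 5′ U. Opposite-strand pairs of 24 to 30 nt reads overlapped by exactly 10 nt, the mark of the ping-pong cycle in which piRNAs of opposite strands make one another, in 39.2% of pairs in Tdrkh-/- and 39.7% in Tdrkh+/-, against 4.17% if all overlaps of 1 to 24 nt were equally frequent. The order of the libraries turned with distinct sequences (9.55% and 6.92%), at 26 to 28 nt (27.7% and 21.6%) and with sequences that match a single gene (32.3% and 11.2%). At 31 to 37 nt the share was 52.6% in Tdrkh-/- and 29.9% in Tdrkh+/-, but 9.54% and 8.38% with each distinct sequence counted once.

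By reads, repeat sequences were the source that stood out in the knockout, though whether exact repeat matches had been removed from either list is not known. Sequences matching transcripts of more than 20 genes made up 6.93% of 31 to 37 nt reads in Tdrkh-/- and 2.00% in Tdrkh+/-, 16.2 times as many per microRNA read (16.1 to 16.3). The ratio of these long shares, 3.46 by reads, turned to 0.604 with each distinct sequence counted once, and was 1.32 so counted at equal numbers of long reads, both chosen after seeing the data. At 24 to 30 nt they made up 7.72% and 1.43%, and per microRNA read their ratio was 2.41 where that of reads sense to protein-coding genes was 0.451. Long reads found antisense to genes alone were 7.93 times as frequent per microRNA read, long reads sense to pseudogenes 8.04 times, long reads sense to protein-coding genes 4.74 times and those sense to long noncoding genes 4.41 times. Within messenger RNAs, 3′ untranslated regions held 73.8% of the 24 to 30 nt reads in Tdrkh-/- and 70.7% in Tdrkh+/-, on 44.2% of the bases. At 31 to 37 nt the 3′ untranslated share was 73.6% and 64.7%, and the coding share 23.9% and 31.7%.

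Most host genes of piRNAs showed the same exchange of lengths. Of the 4053 protein-coding and long noncoding genes with at least 500 reads of 24 to 30 nt, 2971 (73.3%) were at least 2-fold lower and 5.50% at least 2-fold higher in Tdrkh-/- per microRNA read, with a median log2 ratio of -1.58. For 31 to 37 nt reads 3141 of these genes were at least 2-fold higher and 52 at least 2-fold lower, with a median of 1.73. Reads of 24 to 30 nt were lower and those of 31 to 37 nt higher in 3469 genes (85.6%), and the ratio of long to 24 to 30 nt reads was higher in Tdrkh-/- in 98.6% of genes, with medians of 2.06 and 0.204. Scaling per read listed shifts every log2 ratio by -0.42 and scaling per transcript-matching read by -0.57, which leaves both medians on their side of 0.

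Among the 10 most abundant hosts, Fth1, the ferritin heavy chain, had 45141 reads of 24 to 30 nt in Tdrkh-/- and 100795 in Tdrkh+/- (log2 ratio -1.24) but 201840 and 23627 of 31 to 37 nt (3.01). Abl2, a tyrosine kinase, had log2 ratios of -1.54 and 2.09 for the shorter and longer reads, Zbtb37 -1.10 and 3.02, and D10Wsu102e -0.86 and 2.37. The long noncoding 1700001L05Rik had -1.92 and 0.60. Klf13, a Krüppel-like transcription factor, had 15742 and 163292 reads of 24 to 30 nt, a log2 ratio of -3.46, and a ratio of 0.96 at 31 to 37 nt. Gm38246 was higher at both lengths, with log2 ratios of 2.17 and 4.13. Its 24 to 30 nt ratio was -0.58 when sequences that match another gene on either strand were left out. Counting sense matches alone, 98.2% of its reads came from sequences in a single gene.

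**Figure D2:**
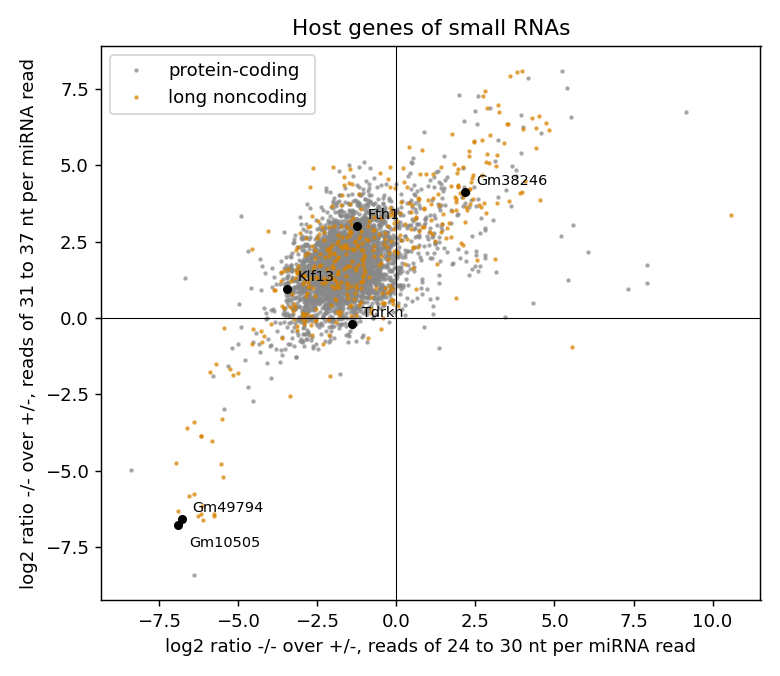
Log2 ratio of Tdrkh-/- to Tdrkh+/- per microRNA read for 24 to 30 nt reads (horizontal axis) and 31 to 37 nt reads (vertical axis), 1 point per gene with counts in both libraries (4040 genes), protein-coding in grey and long noncoding in orange. Most points lie at upper left, lower at 24 to 30 nt and higher at 31 to 37 nt, and Gm49794 and Gm10505 lie at lower left.

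A small set of hosts, mostly long noncoding RNAs, was lower at both lengths. Gm49794 (chromosome 17, 27354111 to 27367492, GRCm38), the most abundant host in Tdrkh+/- among those named, had 4324 reads of 24 to 30 nt in Tdrkh-/- and 452609 in Tdrkh+/-, 111-fold lower per microRNA read, with log2 ratios of -6.79 at 24 to 30 nt and -6.57 at 31 to 37 nt. Its neighbour Gm10505 (27325035 to 27344833) was 119-fold lower, 4930463O16Rik 119-fold and 4933412L11Rik 126-fold. In all, 52 genes were at least 2-fold lower at both lengths, of which 32 were noncoding. Gm21269 and Gm10619, adjacent on chromosome 7 between 73781429 and 73838898 and chosen after their values were seen, had log2 ratios of -6.18 and -6.40. Ifi204 had the lowest ratio, -8.38 (-11.43 to -6.53), but 0.158% of its reads came from sequences that match a single gene.

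The highest gene ratios, but for that of Gm10203, rested on repeat sequences. Gm16195 and Vmn1r224 were at least 4052-fold higher at 24 to 30 nt and Gm45571 at least 4046-fold, each against a floor of 3 counts, and Gm43414 had a log2 ratio of 10.57 (9.59 to 11.78). No more than 0.0466% of the reads of these 4 genes came from sequences in a single gene, and a 27-nt sequence of the B1 repeat, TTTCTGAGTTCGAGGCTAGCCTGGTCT, had 145466 reads in Tdrkh-/- and 0 in Tdrkh+/-. Reads that began with its first 18 nt numbered 320636 and 698, and those 1 base away 78044 and 6657, so the 0 is not read as absence of such RNAs and the bounds hold for exact matches alone. Gm10203 was at least 1281-fold higher, with 91.8% of reads from sequences in a single gene.

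Lists of host genes fixed beforehand differed in how far they followed the rest. Ribosomal protein genes had a median log2 ratio of -2.37 at 24 to 30 nt over 80 members, below every one of 10000 matched random lists, and of 0.64 at 31 to 37 nt; in Rps3 the values were -1.37 and 1.93, in Rpl4 (35.4% of reads in a single gene) -0.29 and 2.31, and in Rps15 (29.95%) -3.64 and -1.04. Histone genes had medians of -2.37 and 0.79 over 72 members, of which 61 were higher at 31 to 37 nt, with -2.49 and 1.75 in Hist1h4n (0.231% of reads in a single gene), -1.93 and 0.90 in Hist1h2bb and -1.81 and -0.33 in Hist1h1a. Early meiosis genes had a median of -2.16 over 13 members, at percentile 1.15 of the random lists, and of 0.21 at 31 to 37 nt, below all random lists and below 0 with either other scaling; Sycp1 had -1.54, Smc1b -0.99 and Hormad1 -2.19 at 24 to 30 nt. piRNA pathway genes had a median of -1.54 over 18 members at percentile 39.4, with Exd1 at -1.45 and Fkbp6 at -1.16, while Piwil2 stood at 0.12, which turns negative per read listed. Spermatogonial genes had a median of -1.37 over 12 members at percentile 67.5, with Zbtb16 at -2.73, Dazl at -1.84 and Lin28a at 0.35, which also turns negative per read listed. Of the somatic genes, Clu of Sertoli cells stood at -0.23, Sox9 at -1.19, Star of Leydig cells at -1.16, Myh11 of peritubular cells at 1.29 and Acta2 at 0.24, the last turning negative per read listed. With a minimum of 20 reads, 10 Sertoli genes had a median of -0.48 at 24 to 30 nt, at percentile 98.6, and of 0.45 at 31 to 37 nt, at percentile 1.54. No gene name held the words pachytene or piRNA, so this list was empty and says nothing on whether such hosts were present.

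MicroRNAs differed little between the genotypes. Of the microRNAs with at least 200 reads, 137 lay within 2-fold as shares of microRNA reads. Mir10b made up 50.4% of microRNA reads in Tdrkh-/- and 52.8% in Tdrkh+/-. Mir470 made up 7.49% and 5.41%, Mir871 4.80% and 4.79%, Mir143 3.60% and 3.97%, Mir10a 2.78% and 4.36% and Mir148a 1.05% and 1.29%. Mir191, Mir99b, Mir22 and Mir127 had log2 ratios of 0.29, 0.22, 0.12 and 0.04, all of which turn negative per read listed. The 4 that were at least 2-fold higher were Mir379 (1.24), Mir196a-2 (1.18), Mir541 (1.13) and Mir1981 (1.06), and none was so per read listed, where 9 were at least 2-fold lower. Mir34c, a member of the mir-34 family of meiotic and later germ cells, was the single one at least 2-fold lower per microRNA read, with 119 and 549 reads and a log2 ratio of -2.29. The next highest were Mir200b (0.91), Mir365-2 (0.90), Mir92b (0.83), Mir423 (0.67), Mir30b (0.66) and Mir184 (0.66), and the next lowest Mir883a (-0.90), Mir378a (-0.83), Mir136 (-0.78), Mir192 (-0.76), Mir101a (-0.74), Mir532 (-0.70), Mir10a (-0.65), Mir878 (-0.62) and Mir463 (-0.55). Mir30b turned to -0.086 when reads were assigned by their first 18 nt.

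Of the microRNA lists, the group of mir-10, mir-99 and related families alone lay outside the middle of matched random lists, with a median log2 ratio of -0.23 over 8 members at percentile 0.83. The X-linked spermatogenic clusters had a median of 0.31 over 15 members at percentile 94, the let-7 family 0.04 over 12, the Dlk1-Dio3 cluster -0.04 over 12, the mir-17 to mir-92a and related clusters -0.04 over 5 and the mir-181 and mir-182 group 0.00 over 8. Cell type microRNAs gave values alone: Mir202 of Sertoli cells 0.16, Mir143 and Mir145a of smooth muscle -0.14 and 0.37, Mir126a of endothelium 0.30, Mir146 of leukocytes 0.54, Mir486 of erythroid cells 0.54 and Mir200b and Mir429 of epithelium 0.91 and -0.50, with a median of -0.52 for the 4 fibroblast members. No member of the muscle list or of the mir-290 to mir-295 and mir-302 clusters reached 200 reads.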

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

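All tests of explanations in this part were chosen after the results they measure were seen. Signals outside the comparisons of the report were reads of 38 to 40 nt, 12.2% of the Tdrkh-/- library and 2.86% of the Tdrkh+/- library, and reads that hold the sequence CTACAGTCCGACGATC, the end of the 5′ adapter, 96380 in Tdrkh-/- and 1784 in Tdrkh+/-.

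The first pattern was the greater length of reads in Tdrkh-/-. A difference in gel selection would move all RNAs, yet the ratio of 31 to 37 nt to 24 to 30 nt reads of structural RNAs differed 1.06-fold between the libraries, against 10.5-fold for reads outside microRNAs and structural RNAs. Adapter bases left on mature piRNAs would end transcript matches, yet 50.2% of the long Tdrkh-/- reads matched a transcript over their whole length, against 44.4% of the 24 to 30 nt Tdrkh+/- reads. A candidate explanation is that 3′ ends stayed where the precursor was severed just before a U: the next transcript base was U for 47.0% of distinct long sequences in Tdrkh-/- and 33.97% in Tdrkh+/-. This stays a hypothesis from 1 library per genotype.

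The second pattern was the set of hosts lower at both lengths, of which the 28 at least 32-fold lower at 24 to 30 nt, with at least 90% of reads in a single gene, had 955768 reads of 24 to 40 nt in Tdrkh+/- and 9733 in Tdrkh-/-. Carry-over from Tdrkh+/- as the source of all remaining reads is argued against. The ratio of long to 24 to 30 nt reads was higher in Tdrkh-/- beyond counting error in 12 of the 28 hosts, up to 18.3-fold. It was lower in 4. The 18.3-fold value, of 4930405N21Rik, rests on 42 long reads and 26 of 24 to 30 nt in Tdrkh-/-. Some hosts are neighbours, such as Gm49794 and Gm10505, so the 28 are not all separate loci. Carry-over may still be the source of most remaining reads at Gm49794 and Gm10505, the 2 most abundant. There the mean length was 28.2 nt in Tdrkh-/- and 28.3 nt in Tdrkh+/-. The other 26 hosts had 28.8 nt and 28.2 nt, so carry-over of part of their reads stays open too. The comparison was 2928 hosts with at least 90% of reads in a single gene, without those at least 2-fold lower at both lengths. They had 32.98 nt in Tdrkh-/-. For the loss itself, fewer meiotic cells in Tdrkh-/- stay a possible cause. Early meiosis genes had a median log2 ratio of 0.21 at 31 to 37 nt against 0.91 to 2.11 in random lists. That shift is far smaller than the loss in the 28 hosts. The list holds early meiosis genes alone and does not measure later cells, so the difference in size decides nothing on this cause. Ribosomal, histone and, with a minimum of 20 reads, Sertoli lists were low too. Reads of an older testis in the Tdrkh+/- library stay open as well, and Mir34c, at -2.29, is what either would give, though the 4 members of its family measured with a minimum of 20 reads had a median of -0.90 and 1 of them was higher.

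The third pattern was the excess of repeat-derived reads in Tdrkh-/-. A few abundant sequences as the whole cause are argued against by the ratio of long repeat shares without the 10 most abundant of each library, 3.27 against 3.46 with them, though it was 2.52 without 100 and 1.78 without 1000. With each distinct sequence counted once that ratio was 0.604; this count was the first test run and was replaced after its value was seen, and at equal numbers of long reads it was 1.32, from 1.30 to 1.32 over 10 draws. Small RNAs do not measure the LINE-1 RNA of the tissue, so whether it differed stays untested.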

How the results depend on the processing

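The settings with sequences in 1 gene alone, per transcript-matching read and both for the repeat share were chosen after seeing the data. So was the setting without sequences of at least 1000 reads in 1 library and 0 in the other. The ratios of 24 to 30 nt reads stayed below 1, those of long reads above 1 and the excess of A at position 10 above 0 under every setting run for them. No paired analysis was possible because there is 1 library per genotype, which also rules out leaving out a replicate. Not run, for want of a genome sequence, were sequences with 1 genome match, scaling per genome-matching read, and regions of either size. The intervals cover counting error alone and are narrow at this depth; 64 of 198 values stayed within them or within 1.5 times the count. Where a value reversed, the cause was not tested but for the repeat share.

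With each distinct sequence counted once, the 24 to 30 nt share ratio was 0.397 (per microRNA 0.525), the long share ratio 2.47 (3.27), the 5′ U difference -3.00 points at 24 to 30 nt and 6.25 at 31 to 37 nt, the A at position 10 difference 5.02, the 10-nt overlap difference 2.63 (reversed) and the shared 5′ end difference -7.66 (reversed). Without sequences read once these were 0.325 (0.459), 3.82 (5.45), -8.16, -2.44 (reversed), 14.8, -0.586 and -0.240 (reversed). With sequences in 1 gene they were, per microRNA, 0.333 and 4.12, then -3.75, 7.93, 2.21, 21.1 (reversed) and 5.30. Without sequences of at least 1000 reads in 1 library and 0 in the other they were 0.334 (0.441), 3.53 (4.69), -7.40, -0.0570 (reversed), 13.5, -0.415 and 4.77.

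At 26 to 28 nt the share ratio was 0.205 (0.273), the 5′ U difference -7.51, the A at position 10 difference 16.1 and the 10-nt overlap difference 6.04 (reversed). At 33 to 36 nt the share ratio was 5.16 (6.91), the 5′ U difference 1.56 and the shared 5′ end difference 8.56. Per read listed the ratios were 0.335 and 3.51, and per transcript-matching read 0.302 and 3.16. The difference in the share of transcript-matching 24 to 30 nt reads sense to protein-coding genes, Tdrkh-/- minus Tdrkh+/-, was -12.5 points, and 3.08 points (reversed) with sequences in 1 gene. The ratio of long repeat shares was 0.604 (reversed) with each distinct sequence counted once and 1.32 so counted at equal numbers of long reads.

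The share of genes at least 2-fold lower was 83.3% per read listed, 85.7% per transcript-matching read, 78.5% with sequences in 1 gene and 70.5% with a minimum of 100 reads. Per read listed, 9 microRNAs were past 2-fold, all lower, and Mir191 (-0.13), Mir99b (-0.20), Mir22 (-0.29) and Mir127 (-0.38) reversed. With a minimum of 20 reads, 4 host gene lists in place of 3 lay outside the middle of random lists at 24 to 30 nt, the added one being Sertoli cells. Mir30b reversed to -0.086 by its first 18 nt, and Gm38246 to -0.58 with sequences in 1 gene. Of 139 values of single genes and microRNAs under the alternatives, 60 did not move, 73 moved and 6 reversed.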

Other observations

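All counts in this part were chosen after the data were seen. LINE-1 reads were higher in Tdrkh-/- on both strands when all parts were pooled, but not in every part. Long reads coding for parts of the LINE-1 proteins numbered 1101045 in sense in Tdrkh-/- and 18818 in Tdrkh+/-, 55.3 times as frequent per microRNA read, and 313256 and 7808 in antisense, 37.9 times as frequent. The 10 most abundant sequences held 45.7% of the sense reads in Tdrkh-/- and 35.3% in Tdrkh+/-. At 26 to 30 nt, where reads of most hosts were lower, sense LINE-1 reads were 12.5 times and antisense ones 3.48 times as frequent, but antisense reads of the end of ORF2p 0.808 times. Those of ORF1p, the RNA-binding protein of LINE-1, were 74.4 times as frequent in long sense reads, and a part of ORF2p, the reverse transcriptase, 38.7 times and its end 8.43 times. In long antisense reads the values were 156 times for ORF1p, 6.60 times for the part of ORF2p and 4.64 times for its end. Of long sense LINE-1 reads without a 5′ U, 84.8% in Tdrkh-/- and 83.3% in Tdrkh+/- had A at position 10, against 62.2% and 82.6% at 26 to 30 nt. The reversed protein sequences matched 0 long reads.

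Some sequences were frequent in 1 library and had no reads in the other. Of 3631 sequences with at least 1000 reads in Tdrkh-/-, 51 had 0 in Tdrkh+/- (405941 reads), and of 2251 in Tdrkh+/-, 23 had 0 in Tdrkh-/- (45665 reads). No read of either library began with the first 18 nt of 4 nuclear tRNAs (valine, glycine, glutamate, lysine). Reads 1 base away from the start of tRNA-Glu numbered 1036 in Tdrkh-/- and 6 in Tdrkh+/-. For tRNA-Val they numbered 1821 and 0, for tRNA-Gly 232 and 0 and for tRNA-Lys 594 and 286. For Mir10b, exact starts numbered 1102638 and 1096771. Whether exact matches to such RNAs had been removed from the lists was not settled by these counts. A count of 0 for a single repeat or tRNA sequence is therefore not read here as its absence from the tissue. Removal that differed between the lists would also change the repeat and LINE-1 ratios, which was not tested.

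The base after the 3′ end differed at both lengths. In distinct 24 to 30 nt sequences it was U in 44.1% in Tdrkh-/- and 28.5% in Tdrkh+/-, against 24.04% and 24.7% at the base after that. Distances from 3′ ends to other 5′ ends were counted from -5 to 20 nt. For 3′ ends of distinct 24 to 30 nt sequences, a 5′ end directly after made up 6.60% of pairs in Tdrkh-/- and 4.23% in Tdrkh+/-. At 31 to 37 nt the values were 6.87% and 5.35%. By reads at 24 to 30 nt they were 6.32% and 1.13%, and a distance of 13 nt was the most frequent, at 41.4% and 22.7%.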
